A study of Mus musculus with 14 samples.

How the data were processed

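Peritoneal B-1a cells of Bmi1 KO and WT mice were profiled on one-colour mouse expression arrays. Per the labels, total RNA was extracted with a micro-scale column kit and the cDNA was labelled with Cy3 after a company protocol that is not disclosed, so amplification steps are unknown. Groups were taken from the genotype label. The series text speaks of 2 sets of experiments without saying which sample belongs to which; the set was read from the 2 styles in which sample titles are numbered. Per the file headers, set 1 lay on slide 1 and set 2 on slides 2 and 3, and slide and scan coincided. Slide 2 held 4 KO and 2 WT arrays, and slide 3 held 2 WT arrays.

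Per the file headers, spot intensity was measured with Agilent Feature Extraction 10.7.3.1, with spatial and multiplicative detrending on, local background correction off and surrogate values for dim spots, and positions refer to genome build mm9. The submitters' processing notes name Agilent Feature Extraction. Each array had 62976 spots, of which 59305 were not controls, and these held 55681 probes under 34821 gene names. Other columns of the scanner output gave per-spot marks, scored 0 or 1 per the file headers, for signal well above background, saturation and outliers. The deposited table of processed log2 values has a median of 3.952 in each of its 14 columns and the same distribution in every column. Each column followed the scanner values of its array (Spearman's rho at least 0.9993) and their quantile-normalized log2 values (r at least 0.9995). That comparison settles the log2 scale, the lack of centring by gene and the direction, since higher values mean more signal. What stays unknown is the tool and its exact settings, which are not given in the sources used here. This table was used as an alternative.

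Values analysed here were log2 of the processed intensity minus each array's 75th percentile over non-control spots. Outlier spots were left out, spots of a probe were averaged, and 0 arrays had saturated spots. A probe was kept if well above background on at least 4 of the 7 arrays of either genotype, which left 29687 probes. Each gene name was represented by its probe with the highest mean over all arrays, giving 20413 genes. Of 5639 gene names with several kept probes, 57 had probes that differed in opposite directions at unadjusted p under 0.05. A gene below background on every array of a genotype has only a bound: the brighter genotype's mean is set against the mean, over arrays, of the higher of the probe's own value and the lowest signal among probes well above background. Gene names are those of the array design and can be old. Of 29150 probes with a RefSeq accession, 27509 matched a table of GRCm38.p6 gene names, which was used for current symbols only and never for positions.

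Tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The comparison of genotypes was lmFit and eBayes on all 14 arrays with experiment set as a covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison within each set and the dependence of the difference on the set came from a model with a mean for each genotype in each set. Agreement of the sets was the correlation across genes of their differences, set against 100 assignments of genotype within sets. Single probes were tested by exact permutation of genotype within sets (1400 arrangements). Gene lists were tested with camera at a preset correlation of 0.01, over the 28 of 36 lists with at least 5 measured members, with the estimated correlation and fry beside it. For lists camera and fry used the genes with a value on every array, which left out 76. Camera compares a list with other genes, while fry asks whether a list's genes move, on balance, one way. The estimated correlation ended all 3 camera calls, and fry called 2 lists, Hox genes and follicular B-2 cell genes. Genes within 10 Mb of Bmi1 were compared with other genes by Fisher's exact test.

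The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Bmi1 and Cdkn2a whatever their values; genes past the threshold with a gene symbol, the same sign in both sets and signal above background on every array of the brighter genotype, up to 12 per direction and filled up to 6 by smallest p; up to 4 members of each list by smallest p; 6 genes for the dependence on the set; and 4 per direction for the difference between sets. Some genes that the rule names are not reported here. Lists held Polycomb subunits, cell cycle inhibitors, p53 targets, Hox genes and other developmental regulators, B cell, B-1a, follicular B-2, plasma cell and progenitor genes, pathways of growth, stress and signalling, markers of other cells of the peritoneum, and neighbours of Bmi1.

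Alternatives tried were scaling to probes above background on all 14 arrays, quantile normalization, normexp background correction with an offset of 50, no filter and a filter on all arrays, all probes, a mean-variance trend with robust moderation, array weights, the deposited values, no covariate, slide as a fixed and as a random block, a block on the replicate number, each set alone, and leaving out each array in turn. Leaving out the 4 arrays with under 40% of probes above background, and leaving out the 2 WT arrays without Ddx3y signal, were added after seeing the data. No pair of arrays held identical values (largest r = 0.937 over all probes with a value on every array).

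The steps were tested on simulated data of 20337 genes, with known changes added to some of them. Of 50 genes changed by 2 on the log2 scale 3 were recovered (6%), of 50 changed by 4, 29 (58%), of 50 changed by 6, 46 (92%), and of 50 changed by 8, 49 (98%), with 9 false calls. The simulation applies to the comparison of both sets together. It gave KO and WT the same spread per gene, drew genes independently and held no arrays with few probes above background. In the real arrays the median SD of a gene was 1.83 in KO and 1.03 in WT, so these rates may not hold for them.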

Results

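Gene expression was measured in B-1a cells from the peritoneal cavity of mice lacking Bmi1 and of wild-type (WT) mice. B-1a cells are innate-like B lymphocytes of the body cavities that carry CD5 and secrete natural antibodies, and Bmi1 is a subunit of Polycomb repressive complex 1, which keeps target genes such as Cdkn2a and the Hox genes silent. The comparison asks how the transcriptome of these cells differs without Bmi1. RNA of each sample was hybridised to its own one-colour mouse array, giving 7 Bmi1 KO and 7 WT arrays. They came from 2 sets of experiments, told apart here by the numbering style of the sample titles, with 3 arrays per genotype in set 1 and 4 per genotype in set 2. The labels do not say whether the samples of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

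Signal differed between the arrays and was lower in the Bmi1 KO samples. The share of probes well above background was 43.5%, 59.7% and 63.3% on the WT arrays of set 1 and 54.1%, 47.3%, 46.6% and 51.6% on those of set 2. It was 56.7%, 56.0% and 36.8% on the KO arrays of set 1 and 29.9%, 20.6%, 31.9% and 52.4% on those of set 2. The mean was 40.6% ± 14.4 (SD, n = 7) in KO against 52.3% ± 7.23 (SD, n = 7) in WT (exact permutation test within sets, two-sided, p = 0.0457). The 75th percentile of log2 signal was 6.36 ± 1.73 (SD, n = 7) in KO and 7.46 ± 0.34 (SD, n = 7) in WT (exact permutation test, two-sided, p = 0.0786). On KO set 2 replicate 2, with 20.6% of probes above background, it was 3.61 and lay among probes not well above background. Levels scaled to it can therefore read high on that array. Expression profiles of KO arrays correlated less with one another (mean pairwise r = 0.688 across genes) than those of WT arrays (r = 0.828), and the median SD of a gene was 1.83 in KO and 1.03 in WT on the log2 scale. The 4 arrays with under 40% of probes above background were all KO, and the counts of genes and gene lists past the threshold were also made without them, an alternative chosen after seeing the data.

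**Figure D1:**
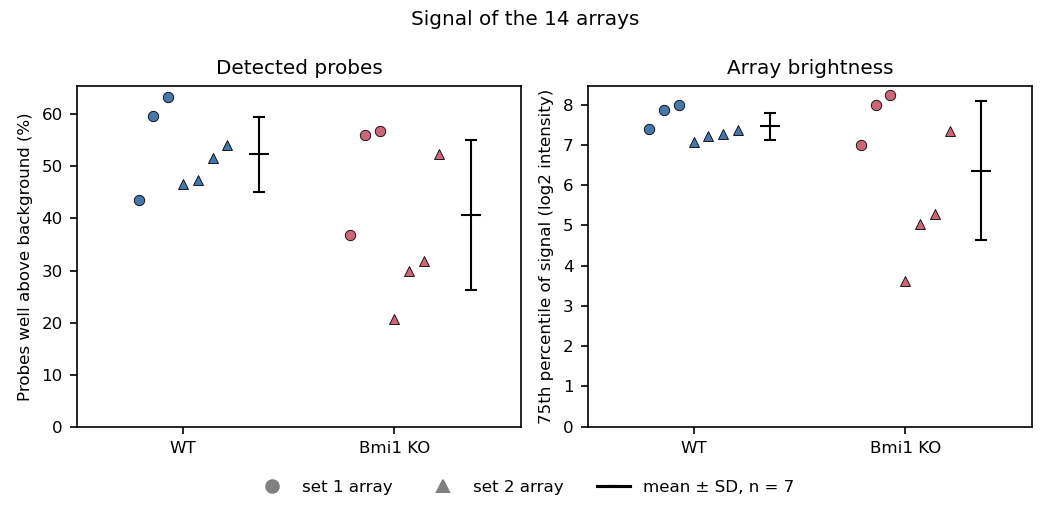
Percent of probes well above background (left) and 75th percentile of signal in log2 intensity units (right) for each of the 14 arrays, with circles for set 1, triangles for set 2, and the mean ± SD of 7 arrays beside each genotype. The 4 KO arrays under 40% of probes lie at 36.8%, 29.9%, 20.6% and 31.9%, below every WT array.

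Bmi1 transcript was read by a pair of probes on chromosome 2 (mm9), and neither was lower in the samples labelled Bmi1 KO. The probe at 18607531 to 18607590 was well above background on 6 of 7 KO and 6 of 7 WT arrays, with log2 levels relative to the array's 75th percentile of 3.00, 2.98 and 1.16 in KO set 1, 0.62, -1.55, 3.78 and 2.58 in KO set 2, 2.09, 1.17 and 1.81 in WT set 1 and -0.30, -3.12, 1.22 and 2.02 in WT set 2. Its KO minus WT difference was 1.10 (SE 0.87; exact permutation test within sets, two-sided, p = 0.28), and turned to -0.25 when scaling used only probes above background on all arrays. The probe at 18607987 to 18608046 was well above background on 5 of 7 KO and 3 of 7 WT arrays, and its mean was -0.25 ± 1.91 (SD, n = 7) in KO and -3.99 ± 1.34 (SD, n = 7) in WT, a difference of 3.74 (exact permutation test, two-sided, p = 0.00286). On single arrays it read -0.15, -1.15 and 0.95 in KO set 1, -3.15, -1.65, 2.62 and 0.79 in KO set 2, -4.87, -3.57 and -2.20 in WT set 1 and -2.22, -5.31, -5.04 and -4.73 in WT set 2. Most of its WT values thus lie at background, where scaled values also follow the brightness of the array. The difference of this probe was smaller with normexp. The part of Bmi1 deleted in these mice is not given in the sources used here, and a probe outside the deleted part checks nothing, so these values do not check the genotype labels.

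Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf and is a classical target of Bmi1, was too dim to enter the genome-wide test. Its probe at 88920405 to 88920464 of chromosome 4 was well above background on 3 of 7 KO and 1 of 7 WT arrays, with a KO minus WT difference of 3.22 on the log2 scale (exact permutation test within sets, two-sided, p = 0.0186). Most arrays of both genotypes thus entered that difference at background, where scaled values also follow the brightness of the array: KO set 2 replicate 3 read -3.21 without signal above background. The probe at 88920543 to 88920602 was above background on 3 of 7 KO arrays and on 0 of 7 WT arrays, with signal at least 2.86-fold higher in KO. KO set 2 replicate 2, the dimmest array, carried the highest level at 4.95 and 5.67. Without it the difference of the first probe was 2.20 and the bound of the second 1.2-fold, and without all 4 dim KO arrays they were 1.88 and 1.02-fold.

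Across 20413 genes, 1 rose and 4 fell in Bmi1 KO B-1a cells at an adjusted p under 0.05. Hoxc9, a homeobox transcription factor of the posterior body axis, rose from -2.53 ± 1.74 (SD, n = 7) in WT to 4.46 ± 2.73 (SD, n = 7) in KO, with 7 of 7 KO arrays above all WT arrays (log2 difference 6.98, SE 1.08, adjusted p = 0.0387). The smallest adjusted p was that of a long intergenic non-coding RNA on chromosome 1 (probe at 175659243 to 175659302, mm9), which fell by 6.30 (SE 0.57, adjusted p = 0.00013), and 4 of its 5 probes, between 175659202 and 175659583, differed by -6.30 to -8.13. The fifth, at 175657865 to 175657924, differed by -0.52. AI607873, an interferon-inducible p200 family gene now named Ifi207, lies in the same interval of chromosome 1. Its brighter probe was above background on 0 of 7 KO and 7 of 7 WT arrays and fell by 4.73 (SE 0.75, adjusted p = 0.0438), a signal at least 11.5-fold lower in KO. A second AI607873 probe, at 175653663 to 175653722, was above background on 0 of 7 KO and 3 of 7 WT arrays and differed by -1.26 (exact permutation test, two-sided, p = 0.267). Ms4a4a, a member of the membrane-spanning 4A family to which the B cell antigen CD20 belongs, fell by 5.83 (SE 0.69, adjusted p = 0.00256) and was above background on 2 of 7 KO and 7 of 7 WT arrays. X53355, an immunoglobulin kappa variable region cloned from a hybridoma that makes antibody to phosphatidylcholine, fell by 6.74 (SE 1.04, adjusted p = 0.0387), from 7.48 ± 0.72 (SD, n = 7) in WT to 0.74 ± 2.87 (SD, n = 7) in KO. KO arrays lay below all WT arrays in 7 of 7 samples for the non-coding RNA, Ms4a4a and X53355, and in 6 of 7 for AI607873. In mm9 the probes of Hoxc9 lay at 102814735 to 102814794 of chromosome 15, of Ms4a4a at 11467221 to 11467280 of chromosome 19, of X53355 at 67846563 to 67846622 of chromosome 6 and of AI607873 at 175666571 to 175671746 of chromosome 1. The non-coding RNA, AI607873 and X53355 lie outside the symbol rule and were chosen after their values were seen.

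**Figure D2:**
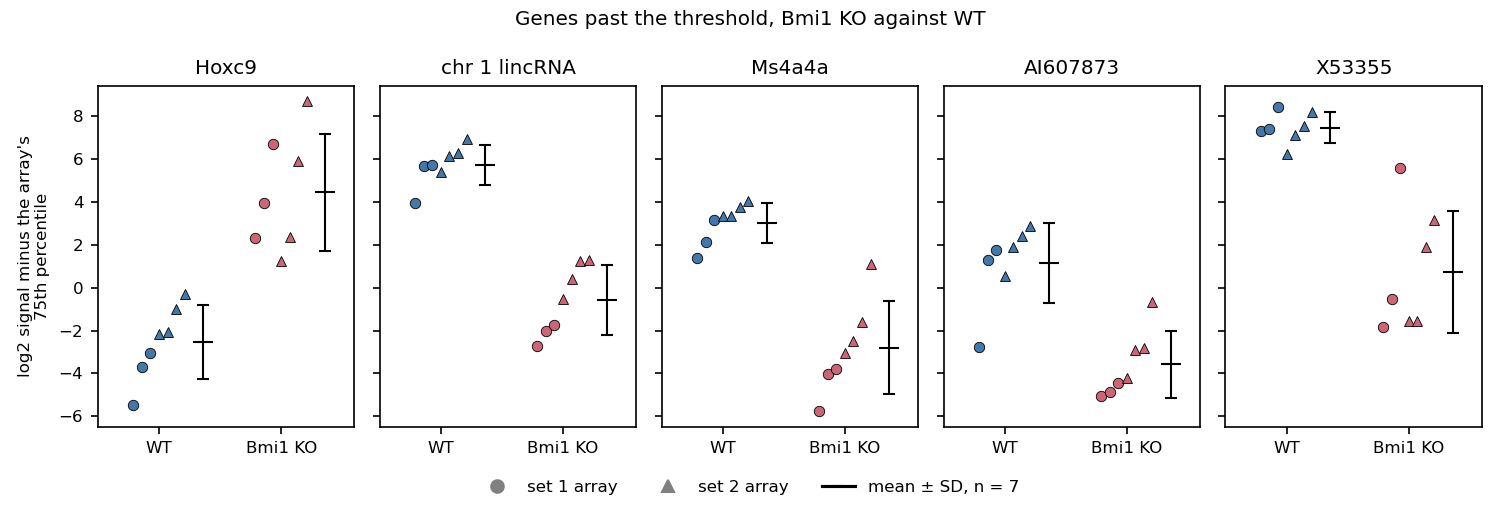
Log2 signal minus each array's 75th percentile for the 5 genes past the threshold, with circles for set 1, triangles for set 2, and the mean ± SD of 7 arrays beside each genotype. For Hoxc9 all KO arrays lie above all WT arrays, and for the chromosome 1 non-coding RNA, Ms4a4a and X53355 all 7 KO arrays lie below all WT arrays.

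The median difference of all genes was 0.47, and gene differences below are given relative to that median, except those of the 5 genes under other settings and others said to be KO minus WT. The p-value of a gene, also over a list alone, tests its KO minus WT difference against 0, before that median is taken off. Relative to all genes the 5 changes were 6.52 for Hoxc9, -6.77 for the non-coding RNA, -5.19 for AI607873, -6.29 for Ms4a4a and -7.20 for X53355. Unadjusted p was under 0.05 for 2047 genes higher and 861 lower, where 1021 are expected by chance. Scaling to probes above background on all arrays moved the split from 1 higher and 4 lower to 1 higher and 60 lower. With that scaling the all-gene median was -0.87, while differences relative to all genes hardly moved, such as -2.79 for Il10 with either scaling. Genes called lower with that scaling, here and below, therefore also follow the moved median. Normexp gave 0 higher and 5 lower, and slide as a fixed block gave 0 higher and 3 lower. Of the 5 genes, 3 passed with normexp, which ended the calls of Hoxc9 (4.72, adjusted p = 0.0711) and AI607873 (-2.24, adjusted p = 0.151). With slide as a fixed block 2 passed, and Hoxc9, X53355 and AI607873 had adjusted p = 0.0954, 0.15 and 0.195. X53355 did not pass with quantile normalization (adjusted p = 0.0684) or the deposited values (0.0683), nor AI607873 without the set covariate (0.123). The non-coding RNA and Ms4a4a passed without each of the 14 arrays in turn. The other 3 calls lay close to the threshold and ended in most of these runs, with differences of 6.34 to 7.67 for Hoxc9, -7.59 to -6.20 for X53355 and -5.24 to -4.40 for AI607873. Hoxc9 passed in 3 of 14 runs, without KO set 1 replicate 3, KO set 2 replicate 1 or KO set 2 replicate 4, and its adjusted p otherwise reached 0.133. AI607873 passed in 3, without KO set 1 replicate 3, WT set 1 replicate 2 or KO set 2 replicate 2 (otherwise up to 0.182), and X53355 in 2, without KO set 1 replicate 3 or KO set 2 replicate 4 (otherwise up to 0.133). Leaving out KO set 1 replicate 3 gave 24 genes and leaving out KO set 2 replicate 4 gave 10, and leaving out any other array gave 2 to 4. Without the 4 dim KO arrays only the non-coding RNA passed (adjusted p = 0.0036), with differences of 5.82 for Hoxc9, -5.27 for Ms4a4a, -5.33 for AI607873 and -4.77 for X53355. Without the 2 WT arrays on which the Y-linked Ddx3y was not well above background, also chosen after seeing the data, the non-coding RNA was again the only one that passed (adjusted p = 0.00379). That fit had 5 WT arrays. The other differences were then 7.01 for Hoxc9, -5.74 for Ms4a4a (adjusted p = 0.0599), -7.01 for X53355 and -4.38 for AI607873, all near those over 14 arrays. Ddx3y was also not above background on KO set 2 replicate 2, which stayed in that fit and had the highest level of the X-linked Xist probe at 100656289 to 100656348 (8.61). The sex of the mice is not given in the sources used here.

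Further named genes did not pass the threshold. Among the smallest p-values of genes higher in KO were those of Cript (2.83, adjusted p = 0.204), Kdm5b, a histone H3 lysine 4 demethylase (1.76, adjusted p = 0.204), Rbfa, a mitochondrial ribosome assembly factor (2.63, adjusted p = 0.213) and Tnfrsf13c, the BAFF receptor that B-2 cells need for survival (2.87, adjusted p = 0.244). KO arrays lay above all WT arrays in 7 of 7 samples for Kdm5b and Rbfa and in 6 of 7 for Cript and Tnfrsf13c. On the lower side were Agbl1 (-6.45, adjusted p = 0.0925), Rlim, an X-linked ubiquitin ligase (-5.27, adjusted p = 0.0925), Opn4, which encodes melanopsin (-3.88, adjusted p = 0.106), Vps37c, an ESCRT-I subunit (-4.20, adjusted p = 0.106) and Fam229b (-4.86, adjusted p = 0.204). Opn4 and Vps37c were below all WT arrays in 7 of 7 KO samples. These lower genes were above background on 7 of 7 WT arrays and on 1 or 2 of 7 KO arrays, so most of their KO values lie at background.

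Hox genes, developmental regulators and classical targets of Polycomb silencing, lay above other genes in KO. Of 39 on the array 11 were measured. Adjusted over the list alone, 5 rose and 0 fell, against 1 over all genes tested: Hoxc9, Hoxb13 (3.45, list-alone adjusted p = 0.00107), Hoxc4 (2.76, 0.00955), Hoxa7 (1.32, 0.0368) and Hoxb9 (0.94, 0.0440), the last named after its value was seen. As KO minus WT, which these p-values test, Hoxa7 and Hoxb9 differed by 1.79 and 1.41. When scaled to probes above background on all arrays they differed by 0.45 and 0.07 (list-alone adjusted p = 0.445 and 0.912). Hoxb13 was above background on 4 of 7 KO and 2 of 7 WT arrays and Hoxc4 on 4 of 7 and 1 of 7, so most of their WT values lie at background. Hox probes above background on 0 arrays also all read higher in KO, such as Hoxb1 (-4.37 against -5.43 in WT) and Hoxd3 (-4.26 against -4.76). Per array, 11.3 ± 5.35 (SD, n = 7) Hox genes were above background in KO and 9.71 ± 3.04 (SD, n = 7) in WT (exact permutation test within sets, two-sided, p = 0.566). The list's median was 0.79 above that of all genes (camera, adjusted p = 0.0129), and the call was lost with an estimated correlation (adjusted p = 0.946). Against no change, and not against other genes, fry gave the list an adjusted p of 0.021. The median relative to all genes was 0.33 with normexp (adjusted p = 0.00903), stayed above 0 under each scaling tried and was 0.63 with slide as a fixed block. It was 0.94 without the 4 dim KO arrays (adjusted p = 0.00368). The count over the list alone ranged from 1 to 6 over the scalings, with Hoxc9 alone when scaled to probes above background on all arrays, and was 2 without the dim arrays (Hoxc9 and Hoxb13).

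Cytoplasmic ribosomal protein genes and B cell identity genes also lay above other genes, with 0 members of either passing singly. Of 75 measured ribosomal protein genes, 74 lay above the all-gene median, by 1.06 at the list's median (camera, adjusted p = 5.8e-12; adjusted p = 0.946 with an estimated correlation of 0.895). Random lists matched on mean signal had a median difference of 1.17, against 1.53 for the ribosomal list before the all-gene median is taken off. Rpl24 (1.62) and Rpl5 (1.78) were among the smallest p-values. With slide as a fixed block the list's median was 1.02, and without the 4 dim KO arrays it was 0.08 above that of all genes (adjusted p = 0.805). Of 29 measured B cell identity genes, which include surface antigens and lineage transcription factors, 24 lay above the all-gene median, by 0.69 at the list's median (camera, adjusted p = 0.0219; adjusted p = 0.946 with an estimated correlation). Pou2af1 (2.02), Ikzf1 (2.20) and Blnk (1.74) led this list. The median difference lay at percentile 71.2 of random lists matched on mean signal. Its direction turned under quantile normalization (-0.12), with the deposited values (-0.12) and without the 4 dim arrays (-0.06), and normexp and slide as a fixed block ended the call (adjusted p = 0.566 and 0.0567). Its adjusted p without KO set 1 replicate 4, WT set 1 replicate 4 or KO set 2 replicate 1 was 0.133, 0.0988 and 0.101.

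**Figure D3:**
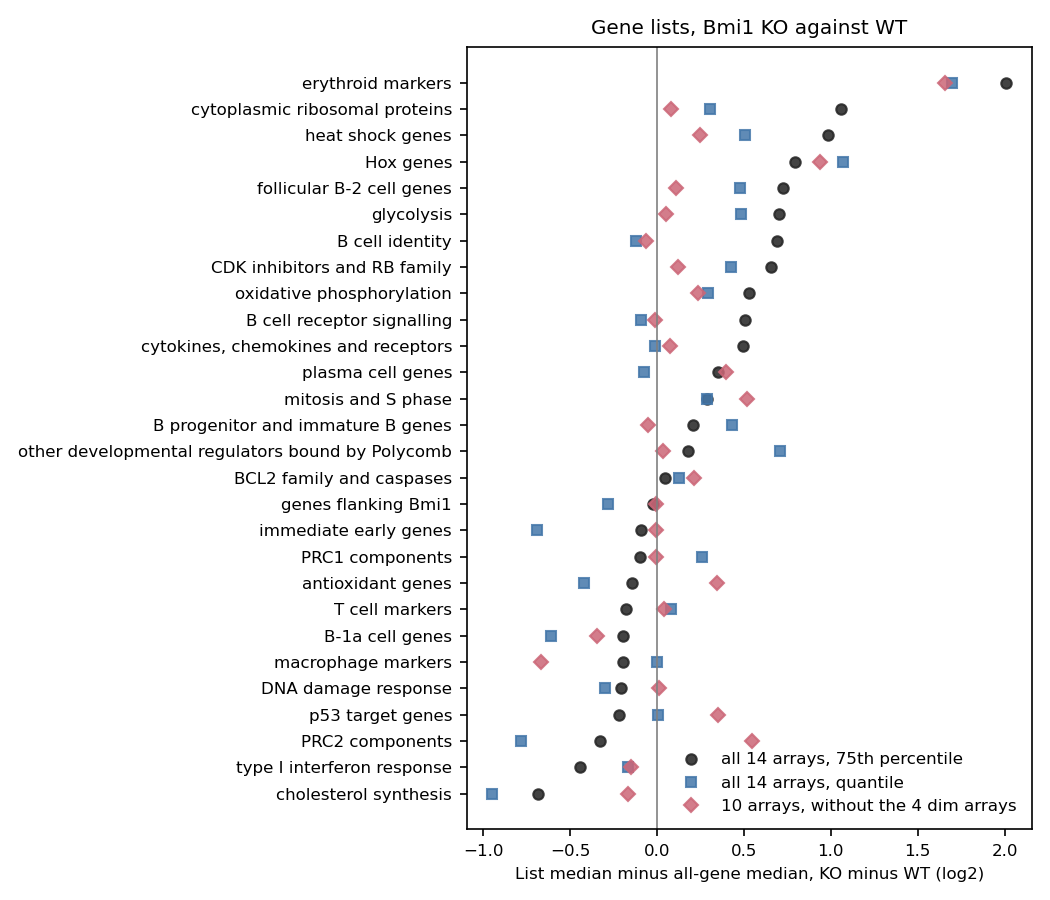
Median KO minus WT difference of each of the 28 tested gene lists minus the all-gene median, in log2 units, for all 14 arrays with the main scaling (circles), with quantile normalization (squares), and without the 4 dim KO arrays (diamonds). The Hox list lies at 0.79, 1.07 and 0.94, while ribosomal proteins move from 1.06 to 0.31 and 0.08 and B cell identity from 0.69 to -0.12 and -0.06.

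Genes that set B-1a cells apart from follicular B-2 cells did not pass as lists, and the difference between the lists was not tested. Among 23 measured B-1a genes, 0 changed over all genes tested and 2 fell adjusted over the list alone. These were Bhlhe41, a transcription factor that B-1a cells need for their self-renewal and repertoire (-5.07, list-alone adjusted p = 0.00769), and Plscr1, a phospholipid scramblase (-4.10, 0.00769), with 6 of 7 KO arrays below all WT arrays for both and signal above background on 4 of 7 KO and 7 of 7 WT arrays. S100a6 (1.32) and Il10, the cytokine of regulatory B cells (-2.79), did not pass with the 75th percentile scaling of all 14 arrays. The B-1a list was 0.19 below other genes at its median (camera, adjusted p = 0.349; adjusted p = 0.946 with an estimated correlation). Its camera adjusted p was 0.00833 with quantile normalization, 0.0332 with normexp and 0.0104 with the deposited values, where an estimated correlation was not run. Among 15 measured follicular B-2 genes, 3 rose and 1 fell adjusted over the list alone. Those that rose included the chemokine receptor Ccr7 (2.70, list-alone adjusted p = 0.0480) and the costimulatory ligand Icosl (2.41, 0.0189), and the transcriptional repressor Bach2 fell (-3.62, 0.0189). Icosl was above background on 4 of 7 KO and 1 of 7 WT arrays and Bach2 on 2 of 7 and 7 of 7. These differences are set against values that lie mostly at background. The follicular list's median was 0.72 above other genes (camera, adjusted p = 0.244; adjusted p = 0.946 with an estimated correlation). Against no change, and not against other genes, fry gave it an adjusted p of 0.0386. Without the 4 dim KO arrays 1 B-1a gene fell over the list alone, Il10 (-3.92, list-alone adjusted p = 0.0466). Il10 also passed when scaled to probes above background on all arrays (0.0146), and was above background on 2 of 7 KO and 7 of 7 WT arrays. Bhlhe41 (-2.99) and Plscr1 (-1.92) did not pass without the dim arrays (0.121 for both), and of the follicular members 1 passed, Icosl (3.78, 0.0274). Ccr7 did not pass with quantile normalization (0.161), Icosl not when scaled to probes above background on all arrays (0.492), and Bach2 not with normexp (0.0655).

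Polycomb subunits and cell cycle inhibitors showed 0 genes past the threshold with the 75th percentile scaling, over all genes or over the list alone. PRC1 components (17 measured, median -0.10, camera adjusted p = 0.829), PRC2 components (10 measured, -0.33, 0.642) and other developmental regulators bound by Polycomb (17 measured, 0.18 at the median but -0.05 at the mean and below other genes by camera, 0.976) did not pass. In the PRC2 list the smallest p-values were those of Rbbp4, at 1.94 ± 1.66 (SD, n = 7) in KO and -0.23 ± 0.92 (SD, n = 7) in WT, and Aebp2, at -2.79 relative to all genes (list-alone adjusted p = 0.0944 for both), and among the developmental regulators Meis1 was at 1.88 and Pax2 at -2.18. The CDK inhibitor and RB family list had a median of 0.66 (8 measured, adjusted p = 0.31), with Cdkn2b, the neighbour of Cdkn2a, at 1.98 and Rb1 at 1.97 (list-alone adjusted p = 0.0594 for both). The p53 target list had a median of -0.22 and a mean of 0.09 (19 measured, adjusted p = 0.991), and Pmaip1 was at 1.83. In set 1 alone the p53 list's median was 0.78 (adjusted p = 0.038). With other scalings some members passed over the list alone. Cdkn2b and Rb1 were higher with normexp (0.0428 for both). Phf19 of the PRC2 list was lower when scaled to probes above background on all arrays (0.0142). Of the developmental regulators 2 were higher and 1 lower with quantile normalization, 0 and 2 with normexp, and 0 and 4 when scaled to the probes above background on all arrays. Cdkn2b was above background on 4 of 7 KO and 1 of 7 WT arrays. Leaving out the 4 dim KO arrays gave 0 members in each of these lists. List medians turned sign in several runs. That of PRC1 was 0.26 with quantile normalization, 0.25 with the deposited values and 0.11 with normexp. That of PRC2 was 0.55 without the 4 dim KO arrays and 0.07 with normexp. That of p53 targets was 0.35 without the dim arrays, 0.26 with slide as a fixed block, 0.07 with normexp and 0.01 with quantile normalization.

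Among immune and B cell programmes, the cytokine and receptor list had 2 members that rose over the list alone, Tnfrsf13c (2.87, 0.0121) and Il9r (1.74, 0.0121), with a list median of 0.50 (22 measured, camera adjusted p = 0.349) that was -0.01 under quantile normalization. Il9r did not pass when scaled to probes above background on all arrays (0.359), and neither passed without the 4 dim KO arrays (Tnfrsf13c 0.251, Il9r 0.143). Il10 was lower without them (0.0446) and when scaled to probes above background on all arrays (0.0209). With normexp 4 members rose, among them Ccr7 and Il21r (0.0375 for both). Trim30a, an interferon-inducible TRIM protein, was the 1 of 21 interferon response genes that rose over the list alone (1.78, 0.0211), while the list's median was -0.44 (adjusted p = 0.829) with Ly6e at 1.84 and Isg15 at -1.82. Trim30a was above background on 4 of 7 KO and 1 of 7 WT arrays, so most of its WT values lie at background. It did not pass under any other scaling tried (list-alone adjusted p = 0.0584 to 0.368) and passed without the 4 dim KO arrays (2.38, 0.0299). Mx2, named after its value was seen and above background on 0 of 7 KO and 5 of 7 WT arrays, was lower without them (0.0299). Scaling to probes above background on all arrays gave 0 higher and 2 lower members, Mx2 (0.00678) and Isg15 (0.00947). Plasma cell genes (18 measured, median 0.35, adjusted p = 0.642), B progenitor genes (9 measured, 0.21, 0.809), B cell receptor signalling genes (27 measured, 0.51, 0.349) and immediate early genes (22 measured, -0.09 at the median but 0.07 at the mean, 0.829) held 0 changed members. Quantile normalization turned the medians of plasma cell and B cell receptor signalling genes to -0.08 and -0.09, and normexp that of immediate early genes to 0.12. Leaving out the dim arrays turned B cell receptor signalling to -0.01 and B progenitor genes to -0.05. Mki67, the proliferation marker, was at 3.12 and E2f1 at -2.49 in the mitosis and S phase list (28 measured, 0.29, adjusted p = 0.900), in which 3 members were lower over the list alone when scaled to probes above background on all arrays. The list of BCL2 family genes and caspases had a median of 0.05 (21 measured, 0.744), with the apoptosis inhibitor Xiap at 2.24 (list-alone adjusted p = 0.0543) and 7 of 7 KO arrays above all WT arrays.

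Metabolic and stress lists gave 1 changed member. Xrcc1, a scaffold of single-strand break repair, was the only one of 31 DNA damage response genes to rise over the list alone (3.92, 0.0415). It was at 1.49 without the 4 dim KO arrays (list-alone adjusted p = 0.599) and did not pass with quantile normalization (0.0869) or scaling to probes above background on all arrays (0.0736). The list's median was -0.21 (adjusted p = 0.642), 0.12 with normexp and 0.01 without the dim arrays. Oxidative phosphorylation genes (66 measured, median 0.53, adjusted p = 0.190), glycolysis genes (18 measured, 0.70, 0.190), heat shock genes (10 measured, 0.99, 0.224), antioxidant genes (21 measured, -0.15, 0.976) and cholesterol synthesis genes (17 measured, -0.69, 0.436) did not pass. Uqcrh (2.05), Ldha (1.36), Hsp90ab1 (1.45), Txn1 (1.26) and Lss (-2.74) had the smallest p-values of these lists. Lss (0.015) and the antioxidant gene Gclm (0.0316) were lower over the list alone when scaled to probes above background on all arrays, and Uqcrh was higher with normexp (0.0399). The antioxidant median turned to 0.35 without the dim arrays and 0.19 with slide as a fixed block.

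Markers of other peritoneal cells did not pass as lists. Macrophage markers (13 measured, median -0.20, adjusted p = 0.744) and T cell markers (13 measured, -0.18, 0.991) showed 0 changed members, with Csf1r at 0.22 and the lysozyme gene Lyz2 at -2.73, and with Lat at 0.86 and Cd247 at -2.76. The T cell median was 0.08 under quantile normalization and 0.04 without the dim arrays, and the macrophage median 0.51 with slide as a fixed block. Erythroid markers had a median of 2.01 (5 measured, adjusted p = 0.744), and the haemoglobin gene Hba-a2 varied widely in both genotypes, at 0.24 ± 3.21 (SD, n = 7) in KO and -2.72 ± 2.99 (SD, n = 7) in WT. The keratins Krt8 (-3.54, list-alone adjusted p = 0.0044) and Krt18 (-2.28, 0.0225), the only 2 measured members of the mesothelial and stromal list, fell over the list alone, and without the 4 dim arrays Krt8 passed (0.028) and Krt18 did not (0.129). Krt8 was above background on 2 of 7 KO and 6 of 7 WT arrays. Too few members were measured to test the lists of NK cells (3, median 0.02), mast cells (2, -1.36), granulocytes (4, 0.33), dendritic cells (4, 0.54), the fetal Lin28 programme (4, 0.39), immunoglobulin constant regions (2, -0.30) and sex-linked genes (4, -0.41), and 0 of their members passed over the list alone with all 14 arrays and the 75th percentile scaling. Among these, the medians of sex-linked genes (0.68) and immunoglobulin constant regions (0.16) were above 0 without the dim arrays, and that of NK cells was -0.05 with normexp. The RNA-binding protein Igf2bp3 of the fetal programme was at 2.88 (list-alone adjusted p = 0.0798). It passed without the 4 dim KO arrays (3.82, 0.00834) and with normexp (0.0147), as did the dendritic cell gene Zbtb46 (3.21, 0.032, and 0.0272 with normexp).

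Within the sets of experiments the same comparison gave 0 higher and 2 lower genes in set 1, and 0 higher and 1 lower in set 2. As KO minus WT, the chromosome 1 non-coding RNA passed in both, at -7.28 in set 1 (adjusted p = 0.00545) and -5.57 in set 2 (adjusted p = 0.0254), and Phf8, an X-linked histone demethylase named after its value was seen, passed in set 1 (-6.38, adjusted p = 0.0439, against -1.81 in set 2). At unadjusted p under 0.05 the counts were 251 higher and 995 lower in set 1 and 2681 higher and 517 lower in set 2, beside all-gene medians of 0.10 and 0.84. Without KO set 1 replicate 3 set 1 gave 87 genes, without KO set 2 replicate 4, the brightest KO array of set 2, set 2 gave 2647 genes, and without the other arrays the counts were 0 to 4. On the slide of set 2 that held both genotypes, with 4 KO and 2 WT arrays, limma called 0 genes, with 809 higher and 351 lower at unadjusted p under 0.05.

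The dependence of the KO minus WT difference on the set was tested directly, and limma called 0 genes, with 987 at unadjusted p under 0.05 and a smallest adjusted p of 0.873. Relative to an all-gene median of 0.91, the smallest p-values were those of Gpr174, a lysophosphatidylserine receptor of lymphocytes (6.58), Zbtb34 (4.82), Ehf (4.70), Inpp1 (5.77), Ghdc (-5.37) and the proteasome subunit Psma7 (-6.53). Gpr174 was above background on 3 of 7 KO and 4 of 7 WT arrays, Zbtb34 and Inpp1 on 1 of 7 and 4 of 7, and Ehf on 0 of 7 and 6 of 7. Ghdc and Psma7 were above background on 4 of 7 and 7 of 7. Many of these values thus lie at background. Across genes, which are not independent replicates, the differences of the sets correlated with Pearson's r = 0.333 and Spearman's rho = 0.341. In both sets 63.2% of genes lay on the same side of the set's own all-gene median. Of 100 assignments of genotype within sets, the real one included, 1 gave an r this high (permutation share 0.01). The lowest r of the others was -0.334. Swapping the genotypes in only 1 set turns the sign of r, so an assignment that was not drawn exceeds the real r. Without the 4 dim KO arrays, which leave 1 KO array in set 2, r was 0.05, and without KO set 2 replicate 2 it was 0.217.

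The sets themselves differed in 105 genes, 95 higher and 10 lower in set 2. Relative to an all-gene median of 0.59, the largest increases that met the symbol rule were Spin2 (3.54, adjusted p = 0.0326), the kinase Sgk2 (3.19), Ddah2 (3.09) and Acot11 (3.09), and the largest decreases were Hras1, a RAS GTPase (-6.71, adjusted p = 0.0387), Msrb2 (-4.98), the Fc receptor gene Fcgr4 (-4.81) and the transcription factor Sp1 (-4.80). Spin2, Sgk2 and Ddah2 were above background on 2 of 7 KO arrays and Acot11 on 0 of 7, with 4 or 5 of 7 WT arrays. Hras1, Msrb2 and Fcgr4 were above background on 4 of 7 KO and 3 or 4 of 7 WT arrays, and Sp1 on 4 of 7 and 7 of 7. Many of these values thus lie at background. The count of 105 genes rested on single arrays and on the scaling. It was 409 without KO set 2 replicate 4, 195 without WT set 1 replicate 4, 22 without KO set 2 replicate 2 and 0 to 6 without any other array, 11 when scaled to probes above background on all arrays and 0 with quantile normalization. Batch and biology of the sets cannot be told apart here.

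Genes around Bmi1 were compared with the rest because a targeted allele can carry flanking sequence of another strain. Of 174 measured genes within 10 Mb of Bmi1, 0 passed, against 5 of 20029 elsewhere (Fisher's exact test, two-sided, p = 1), and 15 against 2866 had an unadjusted p under 0.05 (p = 0.0295, Fisher's exact test, a lower share near Bmi1). Without the 4 dim KO arrays these were 7 against 1149 (Fisher's exact test, p = 0.413). The fixed list of flanking genes had 11 measured members and a median of -0.02 (camera, adjusted p = 0.744) that turned to 0.02 with normexp and 0.22 with slide as a fixed block, with Mllt10 at -1.89 and Otud1 at -2.14. The smallest p of this list was that of Msrb2, at 0.18 ± 2.84 (SD, n = 7) in KO and -1.78 ± 2.33 (SD, n = 7) in WT (list-alone adjusted p = 0.0983, and 0.0195 with normexp).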

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

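Of the tests in this section, those chosen only after their result was seen were those that leave out the 4 dim KO arrays, the count of the other 3 KO arrays below all WT arrays, the neighbours of the 5 genes, the B-2 cell test and the splits for the agreement of the sets. In other sections, leaving out the WT arrays without Ddx3y signal, the variable-region group and the further chromosome 1 probes were also chosen after seeing the values. Samples far from the others in their genotype were sought in 70 groups of 7 arrays, and 3 were found, where chance gives about 1 in 20 (3.5). AI607873 read -2.75 on WT set 1 replicate 2, against 0.53 to 2.86 on the other WT arrays. The Cdkn2a probe at 88920405 read 4.95 on KO set 2 replicate 2, against -4.17 to -0.82 on the other KO arrays, and -1.66 on WT set 2 replicate 4, against -6.23 to -4.37 on the other WT arrays.

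Ribosomal protein and B cell identity genes lay above other genes in KO, and the 4 dim KO arrays are a candidate explanation, since without them the list medians were 0.0793 and -0.0623. On brightness of the probes, ribosomal genes lay at percentile 100 of 10000 random lists matched on mean signal. The median of these lists was 1.17 against 1.53 (all genes 0.47), and B cell identity genes lay at percentile 71.2. Random lists were drawn gene by gene, while ribosomal genes had an estimated correlation of 0.895. Their percentile therefore does not exclude brightness as the whole cause. Hox genes had a median of 0.94 without the dim arrays and percentile 99.9 among matched lists, and without Hoxc9 the list kept a low p (camera, p = 0.0126; p = 0.136 with an estimated correlation). The Hox median did not shrink without the dim arrays (0.79 with them), which argues against these arrays as the whole cause of that median. Its low camera p without them rests on the preset correlation, as the estimated one was not run there. Over the list alone only Hoxc9 and Hoxb13 passed without them. Brightness and Hoxc9 alone stay open. Matched lists were drawn gene by gene, which leaves out the correlation of Hox genes (estimated at 0.204). The p without Hoxc9 was low only at the preset correlation. Release of Polycomb silencing in the KO is a biological hypothesis that stays open, as 54 of 100 splits of the samples gave as many lists (3, highest other 7), so that chance cannot be excluded for the number of lists.

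The 5 genes past the threshold could reflect transcripts lost or gained on the 4 dim KO arrays, which is argued against as the whole cause for 2 of them: without these arrays the non-coding RNA passed over all genes (-6.88, adjusted p = 0.0036), and Hoxc9 over the Hox list fixed beforehand (5.88 relative to all genes, list-alone adjusted p = 0.000681; 0.211 over all genes). Of the other 3 genes 0 passed with 3 KO arrays left, though these all lay beyond every WT array and the differences went from -5.83 to -5.27 for Ms4a4a, from -4.73 to -5.33 for AI607873 and from -6.74 to -4.77 for X53355 (SD of the 3 KO arrays 3.58, 0.33 and 3.08), and since the genes were picked on these same arrays, that source stays open for them. A chromosome segment of another strain around the genes may also account for part of them, because the non-coding RNA and AI607873 share a locus. Among 164 neighbours within 1 Mb, 28 had an unadjusted p under 0.05, against 2851 of 20034 elsewhere (Fisher's exact test, p = 0.312), which decides nothing, since a segment can differ without moving its other genes. A change that follows from loss of Bmi1 remains open too.

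Lower Bhlhe41 and Plscr1 beside higher Ccr7 might come from follicular B-2 cells in the KO samples, as a hypothesis. The test of this took such cells to lower all B-1a genes alike. The other 21 measured B-1a genes had a median of -0.187 (SD 1.17) relative to all genes, against -4.09 for the smaller fall. Genes that B-2 cells also express need not fall as far, and which of the 21 those are was not measured. That median therefore does not decide. The B-2 gene Bach2 fell, but did not pass without the dim arrays (list-alone adjusted p = 0.543). Follicular B-2 cells thus stay open. Loss of transcripts on the 4 dim arrays cannot be told apart from a change in the cells: for both genes 2 of the other 3 KO arrays lay below all WT arrays, too few to decide, in a test whose bound was redrawn after its first result was seen. On those 3 arrays Bhlhe41 averaged 0.94 ± 3.50 (SD, n = 3) against 4.38 in WT. A change of B-1a gene expression in the KO stays open.

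Other splits of the samples were compared with the real one. For the genes past the threshold in both sets, 1 of 100 splits within sets, the real one, gave as many (5, highest other 1). Chance is thus made unlikely at this number of splits but is not excluded. The real split holds all 4 dim arrays in the KO group, so this comparison cannot tell genotype from these arrays. Set 1 has 10 splits, too few for a share under 0.05, and its real value was 2 with a highest other of 1. In set 2, 2 of 35 splits gave as many (1, highest other 1), so chance cannot be excluded there. For the dependence on the set the real count was 0, so all 100 splits gave at least as many whatever the data, and that comparison says nothing about chance. Its highest other count was 52, which may reflect a structure among the arrays, but the source of that count was not tested. For the difference between sets 1 of 100 splits gave as many (105, highest other 0), so chance is made unlikely at this number of splits, with all 14 arrays and this scaling only. For the agreement of the sets 1 of 100 gave as high an r (0.333, highest other 0.327), in a test chosen after its result was seen. With so close a second value, and an r of -0.334 whose sign turns when the genotypes of only 1 set are swapped, chance is not excluded there. The 105 became 0 with quantile normalization and 0 to 6 without most single arrays, and the agreement of the KO minus WT differences of the 2 sets became 0.217 without KO set 2 replicate 2 and 0.0516 without the 4 dim KO arrays.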

How the results depend on the processing

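Leaving out the 4 dim KO arrays and the 2 WT arrays without Ddx3y were alternatives chosen after seeing the data. The 5 genes past the threshold kept their sign under every setting in which they were tested, and the cause of the changes below was not tested, except that fewer samples or genes were tested where arrays, sets or probes were left out. Signal over background limits what can be called: KO arrays averaged 40.6% of probes above background. Scaling to probes above background on all arrays gave 60 lower genes beside an all-gene median of -0.87. With it 8 lists passed, set 2 gave 6 genes and the sets differed in 11. Lists that newly passed were follicular B-2 (0.724), oxidative phosphorylation (0.527), glycolysis (0.700), heat shock (0.985) and erythroid (2.01) genes. Quantile normalization and the deposited values each gave 1 gene in set 1, 6 in set 2 and 0 between the sets. Normexp gave 0 genes higher, 1 in set 1 and 0 between the sets, and 1.86 for the second Bmi1 probe. No filter gave 911 genes different between the sets, and the filter on all 14 arrays 0 higher, 1 lower, 1 in set 1, 0 between the sets and an agreement r of 0.443. All probes gave 8 lower, 7 in set 1, 4 in set 2 and 0 between the sets. Trend with robust moderation gave 1 in set 1 and 0 in set 2. Array weights gave 3 higher and 15 lower genes, 6 lists, 294 genes in set 1 and 439 between the sets. Slide as a fixed block gave 0 higher, and within the slide of set 2 with both genotypes 0 genes passed. Set 1 alone gave 0 higher, 0 lower and 7 lists, and set 2 alone 0 higher and 0 lower. Without the 4 dim arrays there was 0 higher and 1 lower, 1 list, 0 genes in set 1 and 0 in set 2, 1 gene dependent on the set, 1 between the sets, and the agreement of the KO minus WT differences of the 2 sets was r = 0.0516. Without the 2 WT arrays there was 0 higher and 1 lower, 0 in set 1, 0 in set 2 and 0 between the sets. The agreement r was 0.447 over genes with unadjusted p under 0.05 in set 1 and 0.464 for set 2, and the estimated correlation left 0 lists.

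Leaving out each array in turn gave 0 to 5 higher and 2 to 19 lower genes, 2 to 5 lists, 0 to 87 genes in set 1, 0 to 2647 in set 2, 0 to 0 dependent on the set, 0 to 409 between the sets, r of 0.217 to 0.350, and 0.52 to 1.59 and 3.20 to 4.22 for the Bmi1 probes. The B-1a list newly passed under quantile normalization (-0.611), normexp (-0.390), no filter (-0.468), the filter on all arrays (-0.502) and the deposited values (-0.612). Array weights added oxidative phosphorylation (0.655), glycolysis (0.835) and heat shock (0.824), and set 1 alone added plasma cell (0.854), oxidative phosphorylation (1.05), heat shock (1.35) and erythroid (6.41) genes. B cell identity no longer passed with normexp (0.237), no filter (0.414), the filter on all arrays (0.168), slide as a fixed block (0.632), in set 1 alone (0.460) and without the 2 WT arrays (0.485), and ribosomal proteins not without the 4 dim arrays (0.0793). Leaving out single arrays moved B cell identity from 0.440 to 0.925, oxidative phosphorylation from 0.102 to 0.781 and glycolysis from 0.491 to 0.976. The B cell identity list reversed under quantile normalization (-0.12), the deposited values (-0.12) and without the 4 dim arrays (-0.0623), and the p53 target list in set 1 alone (0.781). Of 4824 other values of named genes under an alternative, 4741 kept their direction and side of the threshold or changed sign without a call, 61 no longer passed, 22 newly passed and 0 reversed. A random block on slide gave 1 higher and 6 lower genes; camera was not given a random block, so lists were not run with it, and the comparisons within and between sets were not run with changed blocks or with 1 set alone.

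The replicate number was also used as a block of 7 pairs within sets. Deviations of same-numbered samples correlated over 0.1 in 1 of 7 pairs, and in 1 of 7 the own number was the best match, so the samples share only a number. The replicate block gave 1 higher and 4 lower genes and 3 lists, with 4 of the 5 genes among them, and AI607873 no longer passed (adjusted p = 0.11).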

Other observations

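Immunoglobulin variable regions were looked at after the fall of X53355 was seen, so this group and its tests were chosen after seeing the values. Of 138 measured variable-region or antibody-chain sequences, 72 on chromosome 6 and 64 on chromosome 12, 66 lay above and 72 below the all-gene median, and adjusted over this group alone 4 rose and 3 fell. The 3 that fell were X53355 (-7.20 relative to all genes, group-alone adjusted p = 0.00105) and the heavy chain clones JX120281 (-6.04, 0.0323) and JX120259 (-4.79, 0.0428). The 4 that rose were kappa light chain sequences, U18580 (2.03, 0.0323), DQ372760 (1.95, 0.0323), ENSMUST00000103349, which is kappa variable 4-69 (1.80, 0.0397), and AY351698 (1.74, 0.0428). All 7 kept their direction under each scaling tried. Without the 4 dim KO arrays 96 lay above and 42 below the all-gene median, 0 rose and 1 fell over the group alone, and of the 7 only JX120281 passed (-4.24, 0.00243), with X53355 at -4.71 (0.076). Probes of related variable regions can bind one another's transcripts, so these values do not name a germline gene.

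On chromosome 1 further probes in and beside the interval of the called non-coding RNA were looked at, chosen after seeing the values, and their differences are given as KO minus WT, before the all-gene median of 0.47 is taken off. On the opposite strand, the probes at 175655065 to 175655124 and 175657599 to 175657658 differed by -2.54 and -2.75 on the log2 scale, with exact permutation p = 0.00714 each, while those at 175653734 to 175653793 and 175655106 to 175655165 differed by 0.63 and 0.49. Of the other 4 opposite-strand probes, those at 175653663 to 175653722, 175655046 to 175655105 and 175657659 to 175657718 differed by -1.73, -0.81 and -0.07, and the first was above background on 0 of 7 KO and 4 of 7 WT arrays. The last, at 175657539 to 175657598, averaged -0.26 in KO and 0.74 in WT (exact permutation p = 0.317). The neighbouring p200 family genes did not share the fall: Ifi204 differed by 0.57, Mndal by 1.30 and Ifi203 by 0.87 at its brightest probe, each well above background on 7 of 7 arrays of both genotypes.

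Whole-array detection was compared between genotypes. Among 55681 probes, 11 were well above background on all WT arrays and on no KO array, 0 showed the opposite, and 7078 were above background on all 14 arrays. When the 4 dim KO arrays, which had 20.6% to 36.8% of probes above background, were left out, 13 probes were above background on all 7 WT and on none of the 3 KO arrays, and 34 showed the opposite.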
